A study of Mus musculus with 2 samples.

How the data were processed

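Gene expression was measured by RNA sequencing in 2 libraries of newborn mouse heart, each from 13 pg of RNA. Per the labels, RNA was extracted with a mirVana kit and the protocol named for the libraries is a Smart-seq one. The authors deposited 1 gene table and 1 transcript table per library, with no pooling of replicates. Per the file headers, the tables hold expected counts, estimated reads per gene or transcript that need not be whole, together with posterior means and posterior SDs of the count. Per the file headers, they also hold TPM, which scales the estimated counts by effective length to 1000000 over all features, spike-ins included. The deposited transcript tables give each transcript's share of its gene in percent. Text notes deposited with the tables name the mm10 assembly and the GENCODE M4 annotation, and say that the tables derive from transcriptome alignments. The aligner, the quantifier and their versions are not given in the sources used here. Signal tracks and alignments were not used here.

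Each table held 43346 mouse genes, 96 spike-ins and 26248 rows under a bare number with a median length of 73 nt. Deposited TPM was rescaled to sum to 1000000 over mouse genes, leaving out spike-ins and the rows under a bare number. Gene names, types and positions came from GENCODE M21 on the same assembly, matched by gene identifier without its version, and 42462 of the 43346 genes matched. The 884 others held 0.115% of TPM in each library. The authors' annotation release and this one differ, so a gene model can differ between them. For 2218 genes the deposited effective length was 0, so that their TPM is 0 whatever their true level. Short genes have effective lengths well below their length, and their TPM is the less certain for it. Reads were not assigned by molecular identifiers, and near-identical copies and overlapping genes share reads by estimation. A Smart-seq protocol is named and no strand rule for counting is given in the sources used here, so antisense partners are not separated.

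Depth was about 40648700 expected counts in replicate 1 and 33173400 in replicate 2, of which 39671900 and 32751900 were on mouse genes. By counting error alone, a count of 0 allows up to 3 counts, or 0.0756 and 0.0916 counts per 1000000. Shares of genes carry exact Clopper-Pearson intervals at 95%.

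The labels name 1 group and 2 biological replicates from separate pups, and both carry the same donor identifier. No test between groups was therefore made. Levels are the mean ± SD of the 2 libraries. Genes were called read at 1 TPM or more. Correlations were computed across genes on log2(TPM + 1), with 1000 bootstrap resamples of genes. The SD per library is the SD of the log2 ratio of the libraries over genes of 1 level, divided by the square root of 2. Spike-ins were compared with genes in the same ranges of mean counts, with each set scaled to its own total count.

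For the 30 gene lists, the median log2 ratio of members with a mean of 5 TPM or more was set against 10000 random lists of the same size drawn from 20 strata of mean expression, where at least 3 members could be tested. This describes these libraries and is not a test across hearts. Fold changes on the log2(TPM + 1) scale understate those of weakly expressed genes. The symbols Hbb-b1, Hbb-b2 and Ahsp were not found by name. A pair of genes was described as different when the log2 ratio had 1 sign in both libraries and its mean exceeded 2 SD.

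The gene lists, the pairs, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the members of the pairs, up to 4 members with the highest mean in each list and the member with the largest difference, the 15 protein-coding nuclear genes with the highest mean, the 10 highest and 10 lowest ratios among genes with a mean of 50 counts and 20 TPM or more, and the genes of the transcript list. The 4 pseudogenes of chromosome 1 were chosen after their values were seen. Alternatives covered the pseudocount (0.1), filters on low values, expected counts or posterior means in place of TPM, the median absolute deviation in place of the SD, TMM factors of edgeR 4.0.16 and size factors of DESeq2 1.42.0 on expected counts rounded to whole numbers, and leaving out each replicate. Expected counts replaced TPM only for the correlation, the genes read, the pairs and the mitochondrial share. Posterior means did so only for the genes read, the pairs and the transcript shares. The list comparison and the spread by TPM level were not repeated in either.

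Pseudogene copies of ribosomal protein genes were found by aligning pseudogene transcripts with minimap2 2.31-r1302, at 90% identity over 50% of the length or more. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. The list comparison and the spread were tested on simulated data in which counts for the 43346 genes were drawn from the observed means, SDs and library sizes. Genes missed outright by 1 library were not modelled, so the rates apply to data without such misses. Genes were drawn independently, while members of a fixed list can vary together, so the rates apply to lists of independent genes only. Over 10 simulations, unshifted lists were called in 1.3% of 150 cases at either level, and the SD at 1000 TPM or more came back as 0.438 where 0.441 was put in.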

Results

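RNA from the whole hearts of newborn mice of the B6NCrl strain was profiled at the input of a single cell. Each of the 2 libraries was made from 13 pg of RNA longer than 200 nt, given in the labels as 1 cell-equivalent. Replicate 1 came from the heart of pup 1 and replicate 2 from the heart of pup 3, both at postnatal day 0. The libraries form 1 group, so there is no treatment or control, and the comparison that the design implies is how well RNA at this input gave the same picture of the newborn heart in separate pups. Replicate 1 held about 40648700 expected counts and replicate 2 about 33173400. Spike-in RNA of known sequence made up 2.40% of the counts in replicate 1 and 1.27% in replicate 2. Values below are TPM, transcripts per 1000000, over mouse genes, with the SD over the 2 libraries. No test between groups exists here, and a difference between the libraries is a difference between 2 hearts, 2 RNA aliquots and 2 amplifications together, with no replicate check. Reads were counted without molecular identifiers, so intervals and count limits cover counting error only.

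Among protein-coding nuclear genes, those of the contractile apparatus led the mean of the libraries. Actc1, the cardiac alpha-actin gene on chromosome 2 (114047282 to 114053548, minus strand, mm10), had the highest mean, at 18725 ± 6767 TPM (SD, n = 2). Myl2, the ventricular myosin regulatory light chain, followed at 10514 ± 7682 TPM, and the troponin T gene Tnnt2 stood at 8948 ± 308 TPM. Myl3 averaged 8678 ± 2835 TPM and the tropomyosin gene Tpm1 8068 ± 417 TPM. The 25 fixed sarcomere genes were all read at 1 TPM or more in both libraries and together took 7.41% of TPM in replicate 1 and 10.3% in replicate 2. Fuel and energy genes made up most of the rest of the leading 15, among them Atp5b (6642 ± 2685 TPM), a subunit of ATP synthase, Fabp3 (6066 ± 1268 TPM), which carries fatty acids in muscle, and the mitochondrial ADP/ATP carrier Slc25a4 (5810 ± 230 TPM). Nppa, which encodes atrial natriuretic peptide, stood at 5576 ± 1089 TPM.

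Calcium-handling and excitation genes were read in full, 16 of 16 in both libraries, with Pln, the phospholamban gene, at 1755 ± 306 TPM and Casq2, calsequestrin, at 764 ± 119 TPM. Of the 16 cardiac transcription factors, 12 were read at 1 TPM or more in both libraries, at lower levels: Mef2a averaged 51.0 ± 33.7 TPM, Hopx 46.1 ± 25.0 TPM and Tbx20 45.9 ± 24.7 TPM. Ankrd1, a cardiac ankyrin-repeat gene counted in the same list, was the exception at 658 ± 238 TPM.

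Genes of the other cell types of the heart were present at lower levels than the leading contractile genes. Of 15 fibroblast genes, 13 were read in both libraries, led by the collagen gene Col3a1 (295 ± 40.4 TPM) and Postn (273 ± 26.1 TPM). Of 15 endothelial genes, 14 were read in both, with Fabp4 at 909 ± 114 TPM and Egfl7 at 298 ± 61.2 TPM. The smooth muscle and pericyte list had 8 of 11 genes in both libraries, and its leading member Acta2 (1257 ± 381 TPM) is also used by immature myocytes. Macrophage genes were sparser, with 6 of 15 read in both, for example Lyz2 at 62.3 ± 26.9 TPM. Of 10 neutrophil and lymphocyte genes, S100a8 alone was read in both libraries (53.4 ± 5.44 TPM). S100a9 had 0 counts in replicate 1 and 75.3 TPM in replicate 2, and Retnlg had 15.4 TPM in replicate 1 and 0 in replicate 2.

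Globin transcripts were abundant and nearly equal in the libraries. Hba-a2, an alpha-globin gene, had 2453 TPM in replicate 1 and 2427 TPM in replicate 2, and Hbb-bs, a beta-globin gene, had 1417 and 1425 TPM. The globin copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are nearly identical, so the split of reads within each pair is uncertain. Bpgm, which makes the red-cell effector 2,3-bisphosphoglycerate, was by contrast read at 52.5 TPM in replicate 2 and 0.0104 TPM in replicate 1. Alas2 of the same list, named after its values were seen, had 12.8 TPM in replicate 2 and 0 counts in replicate 1. Of 8 erythroid genes with a mean of 5 TPM or more, Bpgm and Alas2 were the 2 over 2-fold apart.

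Markers of neighbouring tissues were mostly unread. None of the 6 lung genes and none of the 6 thymus genes reached 1 TPM in either library. At these depths a count of 0 allows up to 0.0756 CPM (counts per 1000000) in replicate 1 and 0.0916 in replicate 2 (3 counts). That limit covers counting error only and does not bound the level in the heart. Of genes at 10 to 30 TPM in replicate 1, 23.4% had under 3 counts in replicate 2. Of 10 Schwann cell and neuronal genes, 1 passed in 1 library, Tubb3 at 1.23 TPM in replicate 1. Of 8 liver genes, Trf alone was read (33.8 ± 20.8 TPM), with albumin (Alb) and Afp at 0. Of 10 skeletal muscle genes, Ckm was read in both (4242 ± 348 TPM), a creatine kinase gene that the heart also uses, while Mylpf had 22.1 TPM in replicate 1 and 0 in replicate 2, and Myh3 and Myh8 had 0. Of 6 adipose genes, 2 were read, Cidea at 72.7 ± 25.3 TPM and Fasn at 23.3 ± 16.2 TPM, and Ucp1 and Adipoq had 0.

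Genes of the cell cycle were read in the newborn heart, with 20 of 26 in both libraries: the mitotic kinase gene Cdk1 averaged 235 ± 9.44 TPM, Ccnb1 132 ± 26.6 TPM and Ccnb2 107 ± 4.85 TPM. Of the 24 with a mean of 5 TPM or more, 13 were over 2-fold apart between the libraries. Plk1 differed most, with 0.0104 TPM in replicate 1 and 31.9 TPM in replicate 2. Of 16 imprinted genes, with a median level of 38.5 TPM, 14 were read in both libraries, and the most abundant were Mest at 758 ± 34.2 TPM, Igf2 at 631 ± 105 TPM and the non-coding H19 at 241 ± 2.60 TPM. Of 19 immediate early and heat shock genes, 7 were read in both libraries, and the most abundant, Btg2, averaged 33.9 ± 5.88 TPM.

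Mitochondrially encoded genes took 13.7% of TPM in replicate 1 and 11.9% in replicate 2 (12.8 ± 1.28%, n = 2), or 8.68% and 7.64% of expected counts. The ATP synthase gene mt-Atp6 averaged 28377 ± 2021 TPM and mt-Co1, a subunit of cytochrome oxidase, 11345 ± 3872 TPM. A further 6.75% and 5.10% of TPM lay on 4 annotated pseudogenes of chromosome 1 that copy the mitochondrial genome, Gm28437, Gm28661, Gm29216 and Gm28438. Reads can be shared between these copies and the mitochondrial genes, so the mitochondrial share is uncertain to that extent. The energy lists of the nuclear genome were read nearly in full: 42 of 42 oxidative phosphorylation genes, 23 of 24 fatty acid oxidation genes and 19 of 19 glycolysis genes were at 1 TPM or more in both libraries. Aldoa led the glycolysis genes (3329 ± 418 TPM).

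Related genes were compared in pairs within each library, and 8 of the 16 fixed pairs kept 1 direction with a mean log2 ratio beyond 2 SD. Myh6, the alpha myosin heavy chain of the adult mouse heart, exceeded the fetal Myh7 by 1.21 ± 0.09 on the log2 scale (2.32-fold, n = 2). Reads of these closely related neighbours can be split, and their individual levels are uncertain for that reason. Cardiac Actc1 exceeded skeletal Acta1 by 7.09 ± 1.06, Nppa exceeded Nppb by 3.76 ± 0.75, and the muscle creatine kinase Ckm exceeded the brain form Ckb by 3.31 ± 0.27. The muscle form of carnitine palmitoyltransferase, Cpt1b, exceeded the liver form Cpt1a by 2.92 ± 0.74, and Pgam2 exceeded Pgam1 by 4.92 ± 1.71. Among cytochrome oxidase subunits, the muscle form Cox6a2 was above Cox6a1 by 0.17 ± 0.07, and the muscle form Cox8b was below Cox8a, at −0.53 ± 0.10. With 2 libraries these SDs are themselves rough, and the rule is a description, not a test. A pair without a true difference can pass it. The 0.17 of Cox6a2 over Cox6a1 is below the SD per library of 0.44 for genes at 1000 TPM or more. In expected counts, which are not divided by length, the same 8 pairs passed, with Pgam2 over Pgam1 at 3.73, Cox6a2 over Cox6a1 at 0.41 and Cox8b over Cox8a at −1.29.

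The other 8 pairs did not pass that rule. The adult troponin I gene Tnni3 and the fetal Tnni1 were within their spread (0.22 ± 0.48), with Tnni1 higher in replicate 1 and Tnni3 higher in replicate 2. The ventricular Myl2 against the atrial Myl7 was 0.13 in replicate 1 and 2.83 in replicate 2. Slc2a4 over the fetal glucose transporter Slc2a1 was 1.30 and 2.95, Ldhb over Ldha 0.46 and −0.01, Eno3 over Eno1 0.34 and −0.13, and Myom2 over Myom1 0.88 and −1.23. Cox7a1 over Cox7a2 was −0.17 and −0.35, and this pair passed the rule in expected counts (−1.56 ± 0.13). The mean ratio turned negative in expected counts for Tnni3 over Tnni1 (−0.33), Eno3 over Eno1 (−0.19) and Ldhb over Ldha (−0.08). Erbb4 and Erbb2, the neuregulin receptor genes, were too low to compare, with Erbb4 at 0.969 and 0.0716 TPM and Erbb2 at 0 and 5.09 TPM.

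**Figure D1:**
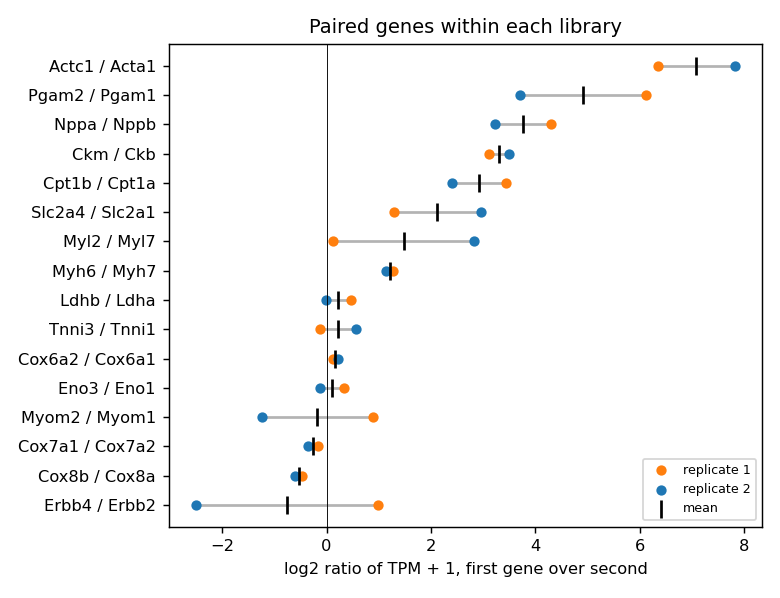
Log2 ratio of TPM + 1 of the first gene over the second for the 16 fixed pairs, with orange points for replicate 1, blue points for replicate 2 and a black tick for their mean. Actc1 over Acta1 has the highest mean ratio (7.09), and Myl2 over Myl7 spans 0.13 to 2.83.

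Of 16 fixed genes, 13 had the same leading transcript in both libraries, but Nexn and Myl6 have 1 listed transcript each, the models of Ryr2 were tied, and Bin1 had no reads in replicate 1. Of the 12 genes that remain, 10 had the same leading transcript, and Mef2a and Fn1 did not. Tpm1-205 held 95.5 ± 0.0071% of Tpm1, Pkm-202 held 91.2 ± 5.25% of Pkm, and Tnnt2-207 held 39.1 ± 3.57% of Tnnt2, ahead of Tnnt2-211 at 28.9 ± 1.80%. Mef2a-208 was the exception among transcription factors, at 95.4% of Mef2a in replicate 1 and 29.2% in replicate 2. For Fn1, the intron-retaining Fn1-202 held 58.4% in replicate 1 and 0.050% in replicate 2. For Ttn, the short model Ttn-215 had the highest share of TPM, at 28.8% in replicate 1 and 69.4% in replicate 2, while most expected counts were assigned to the long Ttn-201, with 96970 against 2817 for Ttn-215 in replicate 1 and 195750 against 25424 in replicate 2. Ryr2 was divided evenly between 2 models of equal length, a split that the reads did not resolve.

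Across genes, the libraries gave a Pearson correlation of 0.829 on log2(TPM + 1) (bootstrap interval 0.823 to 0.835) and a Spearman correlation of 0.771 over 43346 mouse genes, which are not independent replicates. Genes unread in both libraries carry part of that value, since it was 0.534 over genes with a mean of 1 TPM or more. Replicate 1 had 8600 genes at 1 TPM or more and replicate 2 had 8854, and 6649 genes passed in both, 61.5% of the 10805 that passed in either. The counts of the libraries differed far beyond sampling noise (chi-square of 794 per gene over 11666 genes), so they are not 1 library deposited again.

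**Figure D2:**
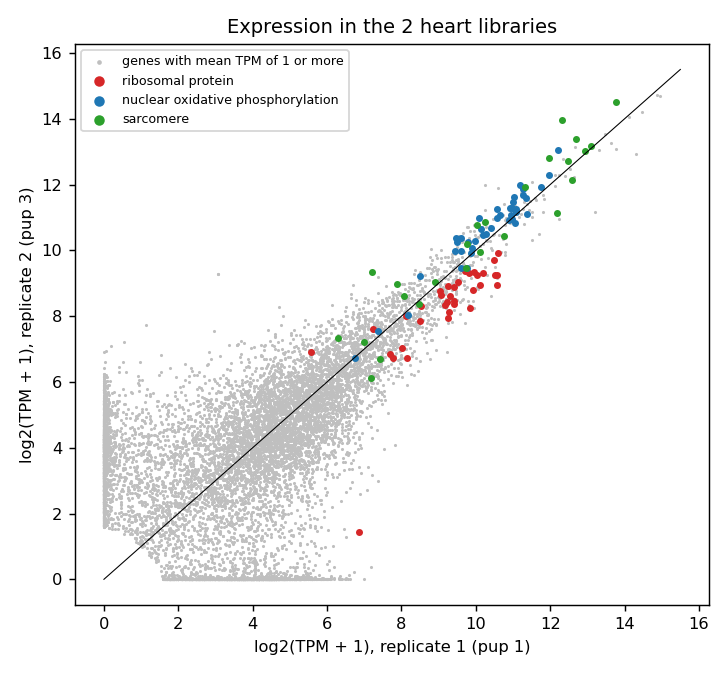
Expression of genes with a mean of 1 TPM or more in replicate 2 against replicate 1, both as log2(TPM + 1), with ribosomal protein genes in red, nuclear oxidative phosphorylation genes in blue and sarcomere genes in green. The line marks equal values, and 33 of the 35 ribosomal protein genes lie below it.

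How closely the libraries matched depended on the level of the gene. Among the 151 genes with a mean of 1000 TPM or more, which include the main sarcomere genes, the SD per library was 0.44 on the log2 scale (bootstrap interval 0.38 to 0.49) and 90.1% lay within 2-fold. Between 100 and 300 TPM the SD was 0.66 and 75.7% of 779 genes lay within 2-fold. Between 10 and 30 TPM, the range of most epicardial genes tested, the SD was 2.05 and 39.0% lay within 2-fold, and the SD was 3.12 with a pseudocount of 0.1 and 1.53 by the median absolute deviation. Between 1 and 3 TPM it was 1.36, a value held down by the pseudocount, since it was 3.04 with a pseudocount of 0.1.

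Weakly expressed genes were often missed altogether by 1 library. Of genes at 10 to 30 TPM in replicate 1, 23.4% had under 3 counts in replicate 2 (exact binomial interval 21.8 to 25.0%), and the reverse share was 23.8%. At 30 to 100 TPM these shares were 8.16% and 7.81%, and at 100 to 300 TPM 0.129% and 0.369%. Above 300 TPM no gene was missed in either direction, with an upper limit of 1.13% for the 325 genes at 300 to 1000 TPM in replicate 1. Above 100 TPM such genes were rare. Mrap and Fgf13 had the most extreme log2(TPM + 1) ratios of genes with a mean of 20 TPM and 50 counts or more. Mrap had 120 TPM and 2974 counts in replicate 2 and 0 counts in replicate 1. Fgf13, on chromosome X, had 127 TPM in replicate 1 and 0 counts in replicate 2. With 3 counts as the floor of the empty library, the share of reads in replicate 2 was 1201-fold higher for Mrap and 1315-fold lower for Fgf13. On that scale Grsf1, with 1 count in replicate 1 and 6031 in replicate 2, was further apart than Mrap, as was Cdk5rap3 (2004-fold). In the other direction Rpa1 (1726-fold) and Grwd1 (1321-fold) were further apart than Fgf13. These folds cover counting error only and set no lower limit on a difference between the hearts, since a gene can be missed by 1 library. Of 4411 genes with a mean of 20 TPM and 50 counts or more, 1722 were over 2-fold apart, 828 of them higher in replicate 2 and 894 higher in replicate 1.

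**Figure D3:**
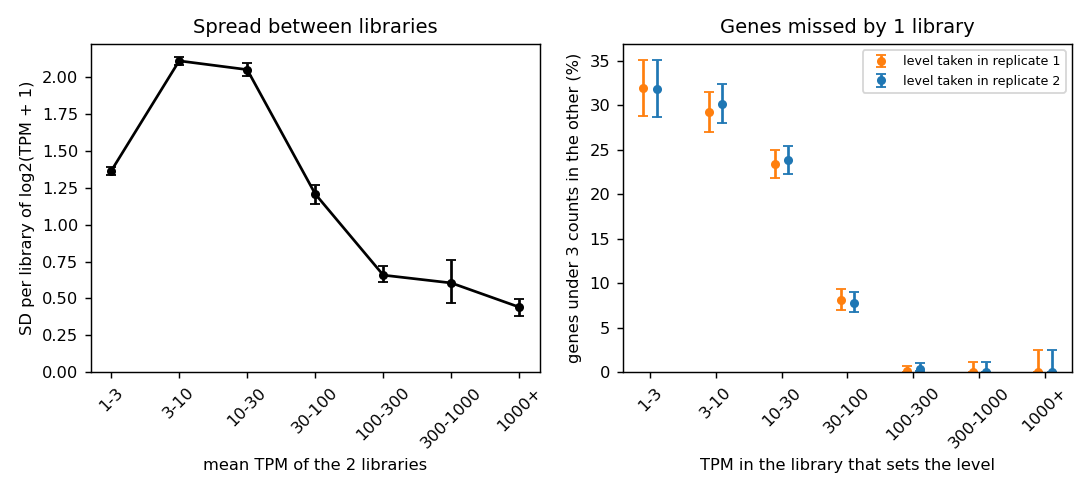
Left, SD per library of log2(TPM + 1) by mean TPM of the gene, with bars for the bootstrap interval over genes. Right, percent of genes with under 3 counts in the other library by TPM in the library that sets the level, with bars for the exact binomial interval. The SD is 0.44 at 1000 TPM or more, and the missed share is 23.4% and 23.8% at 10 to 30 TPM.

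The spread of spike-ins, which were not part of the hearts or of their dissection, was measured in the same way. Above a mean of 10000 counts, 9 spike-ins had an SD per library of 0.25 against 0.51 for 498 mouse genes (difference −0.26, bootstrap interval −0.42 to −0.20). That range has no upper limit, so the counts of spike-ins and genes were not matched within it. Between 1000 and 10000 counts the values were 2.66 for 14 spike-ins and 2.24 for 4711 genes, with an interval of the difference from −1.86 to 1.35. In that range, 2 spike-ins with under 3 counts in 1 library set the spike-in value, which was 0.53 by the median absolute deviation, against 0.91 for the genes. Between 10 and 1000 counts they were 3.99 for 17 spike-ins and 4.59 for 6036 genes, with an interval of the difference from −1.77 to 0.23. Of 21 spike-ins with a mean of 1000 counts or more that were read in both libraries, 20 were lower in replicate 2 per mouse read (median log2 −0.90). Mouse reads per spike-in read were 40.6 in replicate 1 and 77.7 in replicate 2.

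Between the libraries, 5 of the 24 gene lists with at least 3 testable members had a median log2 ratio outside the random range. This range is the central 95% of the medians of 10000 random lists matched on expression. For lists of independent genes, 1.2 of the 24 would be expected outside it. Genes of a list can vary together and some belong to several lists, so that number is no chance rate for the fixed lists. Ratios are given as replicate 2 over replicate 1. The median of genes with a mean of 5 TPM or more was 0.01 in this scaling. TMM and DESeq2 factors, taken relative to the totals of expected counts, gave shifts of −0.07 and −0.11. These shifts were added to TPM ratios as they stand, although TPM and count ratios can differ widely for single genes. Fasn, for example, had a log2 TPM ratio of −1.47 from 3847 expected counts in replicate 1 and 3100 in replicate 2. For ribosomal protein genes the median was −0.78 in TPM and −0.74 in CPM, so values with these factors are approximate.

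Ribosomal protein genes formed the clearest of these groups. They were lower in replicate 2 for 33 of 35 members, with a median log2 ratio of −0.78, and none of the 10000 random lists was as low. Rps14 had 1544 TPM in replicate 1 and 975 TPM in replicate 2, Rplp0 had 1425 and 840 TPM, Rps18 had 1530 and 606 TPM, and Rpl5 had 115 and 1.69 TPM. Pseudogene copies of these genes can share their reads. Nuclear oxidative phosphorylation genes went the other way, with 35 of 42 higher in replicate 2 and a median of 0.31 (percentile 99.7), and the median was 0.20 with DESeq2 factors. Atp5b had 4743 and 8540 TPM and Cox7b 701 and 1332 TPM.

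Atrial genes were lower in replicate 2 for 6 of 7 members tested, with a median of −1.05 (percentile 2.02). Myl7, the atrial myosin regulatory light chain, had 4639 TPM in replicate 1 and 2239 TPM in replicate 2, and Sln, sarcolipin, had 839 and 219 TPM, while Nppa (6346 and 4806 TPM) and Myl4 (1104 and 987 TPM) differed less. The call ended with a minimum mean of 20 TPM (median −0.73, percentile 2.58). The ventricular list lay just inside the range, with 3 of 4 members higher in replicate 2 and a median of 0.71 (percentile 97.47), and Myl2 had 5082 TPM in replicate 1 and 15945 TPM in replicate 2. Epicardial genes were lower in replicate 2 for 5 of 5 members tested, with a median of −4.63 (percentile 0.12): Msln had 79.0 and 8.26 TPM, Aldh1a2, a retinoic acid synthesis enzyme, 38.8 and 0.552 TPM, Krt19 24.4 and 0 TPM, and Upk1b 23.0 and 17.9 TPM. The median was −5.90 (percentile 1.47) with a pseudocount of 0.1 and −3.87 with a minimum mean of 1 TPM. Below the level tested, Lrrn4 (1.36 and 5.47 TPM) and Tbx18 (0 and 0.757 TPM) of the same list, named after their values were seen, were higher in replicate 2. The genes tested lie in the range where single genes were often missed by 1 library. Krt19 and Upk3b had 0 counts in replicate 2 and reached the minimum mean through replicate 1 alone, which fixed their direction. Of the 10 epicardial genes, 3 were read in both libraries, 3 in 1 and 4 in neither. Wt1, Krt8 and Krt18, named after their values were seen, had 0 in both.

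Sex-linked genes were split between the libraries. The Y-linked Ddx3y (chromosome Y, 1260771 to 1286629) had 35.0 TPM in replicate 1 and 0 counts in replicate 2, Eif2s3y had 22.4 TPM and 0 counts, and Kdm5d had 1.08 TPM and 0 counts. Xist, the X-inactivation transcript (chromosome X, 103460366 to 103483254), had 2 counts in replicate 1 and 14.0 TPM in replicate 2. The labels state that sex was not collected. The list median was −4.55 (percentile 1.88) over 3 testable members, or −7.81 with a pseudocount of 0.1. It reflects 2 Y-linked genes against Xist, which differed in the opposite direction, so it describes no common shift, and the other 4 lists outside the random range do not depend on it.

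The other 19 lists lay inside the random range. Sarcomere genes had a median of 0.24 (percentile 94.3) with 17 of 25 higher in replicate 2, and Ttn, which encodes the giant spring protein titin, had 147 and 649 TPM, from 123676 and 251743 expected counts, a smaller ratio. Fibroblast genes had a median of −0.52 (percentile 5.80) with 11 of 14 lower, among them Mfap4 at 62.7 and 0 TPM. Interferon response genes had a median of −2.40 (percentile 6.13) with 5 of 6 lower, led by Bst2 at 67.6 and 0.0511 TPM. The medians were 0.36 for calcium handling and excitation, 0.13 for cardiac transcription factors, 0.26 for endothelial, 0.54 for smooth muscle and pericyte, −0.21 for macrophage, −0.20 for neutrophil and lymphocyte and 0.00 for erythroid genes, and with a minimum mean of 1 TPM the endothelial median turned to −0.11 and the macrophage median to 0.47, a value it also had with a minimum of 20 TPM. They were −0.15 for mitochondrially encoded, 0.19 for fatty acid oxidation, −0.15 for glycolysis, 0.00 for cell cycle, 0.02 for imprinted and −0.97 for immediate early and heat shock genes. The medians near 0 of erythroid, cell cycle and imprinted genes turned negative with TMM and DESeq2 factors, and they were also negative with a minimum mean of 1 TPM for imprinted genes (−0.16) and of 20 TPM for cell cycle genes (−0.19). The median was −0.35 for immediate early and heat shock genes with a minimum mean of 1 TPM and 0.76 for cardiac transcription factors with a minimum of 20 TPM (percentile 93.8). That value of 0.76 rests on TPM and was not checked in counts. Tbx20 (log2 1.13 in TPM) had 5463 and 5170 expected counts and Mef2a (1.43) 4640 and 6405, while Hopx (1.14) had 989.5 and 1980. The list of RNAs usually described as lacking a poly(A) tail, led by the histone gene Hist1h2bc at 89.7 and 227 TPM, had a median of 0.52, and nuclear long noncoding RNAs, led by Malat1 at 6445 and 9116 TPM, had a median of 0.50. In 2 simulated libraries with the SD of these at each level, lists of 20 genes at 300 TPM or more shifted 1.5-fold were called in 58.0% of 50 cases. Lists at 5 to 300 TPM shifted 4.0-fold were called in 86.0% of 50. Genes missed outright by 1 library were not modelled, so these rates may not hold for the real libraries, least of all below 300 TPM. The simulated genes also varied independently, so the rates do not describe lists whose members vary together. Smaller shifts and shorter lists were not simulated.

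**Figure D4:**
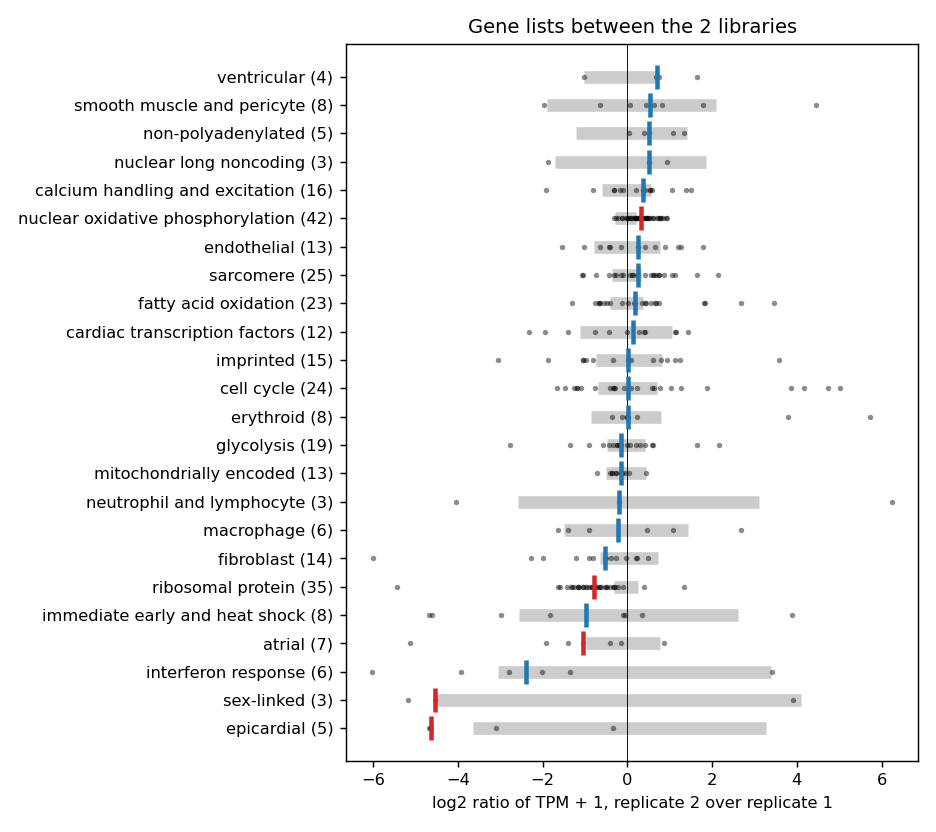
Log2 ratio of TPM + 1, replicate 2 over replicate 1, for the members of 24 gene lists with a mean of 5 TPM or more (points, number of members in parentheses), with the list median as a tick and the central 95% of medians of matched random lists as a grey bar. Red ticks mark the 5 medians outside the bar, from −4.63 for epicardial genes to 0.31 for nuclear oxidative phosphorylation genes.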

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

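The tests of Myl2, of spike-ins, of the cell types against each other, of the joint atrial and epicardial genes and of the Y-linked genes with Xist were chosen only after the values of their genes in both libraries were seen, while those of length, GC content and pseudogenes were written after the pattern but before their own values were seen. The tests of spike-ins, of Myl2, of the joint set and of fibroblast against endothelial genes were left out or replaced for a time once their results were seen, and were then restored as first written. That those of spike-ins, of Myl2 and of the joint set decide nothing by their construction was recognised only after their results were seen.

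Outside the gene tables' named features, the row under the bare number 11364 had 82 expected counts in replicate 2 and 0 in replicate 1, above the 3 counts that an empty row allows.

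Ribosomal protein genes were lower in replicate 2 in 33 of 35 cases, with a median log2 ratio of −0.78. Transcript length and GC content are argued against as the whole cause, since the list lay at percentile 0 of random lists matched on expression and transcript length, and again at percentile 0 of lists matched on expression and GC content. Reads lost to processed pseudogenes are argued against too. In CPM, the median was −0.74 for the genes alone and −0.71 (bootstrap interval −0.89 to −0.57) with the counts of 269 pseudogenes added. Spike-in scaling gave a median of 0.19 per spike-in count (interval −0.04 to 0.35), but 1 factor for every gene cannot set this list apart from other genes, so that test decides nothing. No biological explanation was tested, since the design names only separate pups, and differences between pups, dissections, aliquots and amplifications stay open.

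Of the members tested, 6 of 7 atrial and 5 of 5 epicardial genes were lower in replicate 2. Of 4 ventricular genes tested, 3 were higher in replicate 2, among them Myl2, and Hey2 was lower (34.3 TPM in replicate 1 and 16.3 TPM in replicate 2). Less atrial and epicardial tissue in that sample is a candidate explanation, but the joint set of 12 genes (percentile 0.09 of random lists) was assembled because its lists were low, and its members were uneven, with Myl4 at −0.16, Upk1b at −0.34 and Bmp10, named after its values were seen, at 0.85. Sampling noise of single genes stays open for Myl2, whose percentile of 99.0 among genes of its level is one that some gene must hold. A lower share of all cells other than myocytes would lower their markers alike: the endothelial median exceeded the fibroblast one by 0.77 (bootstrap interval −0.19 to 1.75), too wide to decide, and the epicardial median differed by −4.88 from the endothelial one (−5.50 to −0.60), which goes against it, and by −4.11 from the fibroblast one (−4.52 to 0.18), which does not. The smooth muscle and pericyte median of 0.54 exceeded the epicardial one by 5.16 (0.88 to 5.96), which also goes against it, but differences from the fibroblast (1.05, −0.13 to 2.42) and endothelial medians (0.28, −0.91 to 1.71) include 0, and it stays open because both differences that exclude 0 rest on the same 5 epicardial genes, which are part of the pattern and mostly in the range often missed by 1 library.

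Y-linked Ddx3y and Eif2s3y were read in replicate 1 alone, and Xist, at 2 counts in replicate 1, almost alone in replicate 2. Dropout of single genes is argued against: genes at these levels were missed by the other library in 14.0%, 20.7% and 26.8% of cases, which gives this combination in 0.775% of triplets if misses are independent. A hypothesis is that pup 1 may have been male and pup 3 female. DNA typing of the pups or a record of their sex, not analysed here, would decide it, and a mixed-up sample was not tested.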

How the results depend on the processing

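All alternatives here were planned except the one with the pseudogenes of chromosome 1, which was chosen after seeing the data. No result called in the report reversed. The correlation across genes was 0.805 with a pseudocount of 0.1, 0.811 in expected counts scaled to the library total, 0.534 over genes with a mean of 1 TPM or more and 0.491 over those with 10 TPM or more, where the unread genes are left out. The SD per library at 1 to 3 TPM was 2.05 by the median absolute deviation and 3.04 with a pseudocount of 0.1, and at 1000 TPM or more 0.37 by the median absolute deviation, which gave 5.85 for spike-ins of 10 to 1000 counts, where the SD was 3.99. By the median absolute deviation the spread was 3.15 at 3 to 10 TPM (SD 2.11), 1.53 at 10 to 30 TPM and 0.87 at 30 to 100 TPM (SD 1.21), and with a pseudocount of 0.1 the SD was 3.74 at 3 to 10 TPM and 3.12 at 10 to 30 TPM. Genes read in both libraries numbered 5383 at 5 TPM or more, 7850 at 0.1 TPM or more, 7705 at 5 expected counts or more, 6623 in TPM as deposited and 9352 with posterior mean TPM. Beyond the genes left out and the size of the pseudocount, the cause of these shifts was not tested. The atrial list fell inside the random range with a minimum mean of 20 TPM (median −0.73, percentile 2.58), where fewer genes are tested, and the other 4 lists outside the range stayed outside wherever at least 3 members could be tested. All these list settings used TPM ratios, so no list call was checked in counts, and only the ribosomal protein median was also given in CPM. The mitochondrial share was 8.16% of expected counts, which are not divided by length, and 18.7% with the 4 pseudogenes of chromosome 1, and 11.9 to 13.7% with either replicate left out. Leaving out a replicate gave 312 to 317 of the 418 list genes read. TMM and DESeq2 factors move every ratio alike, so percentiles could not change under them. With 1 library left, the rule for pairs and the match of leading transcripts give no value. No paired analysis was possible because the labels give 1 group. Values of genes under 30 TPM were limited by misses in 1 library (23.4% and 23.8% at 10 to 30 TPM).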

Other observations

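Eef1a1 and Eef2, which encode translation elongation factors, were chosen after their values were seen and stand for no group. Eef1a1 had 4798 TPM in replicate 1 and 1990 TPM in replicate 2 (log2 −1.27), and Eef2 had 756 and 265 TPM (log2 −1.51). Ribosomal protein and nuclear oxidative phosphorylation genes have short transcripts alike, with median lengths of 713 and 631 nt, and differed between the libraries in opposite directions, with medians of −0.78 and 0.31.

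Of 8 genes whose main RNAs are usually described as lacking a poly(A) tail, 6 were read at 1 TPM or more in both libraries and 2 in neither, and whether the RNAs read here carried a tail was not tested. Hist1h1c averaged 136 ± 34.3 TPM and Rn7sk 35.5 ± 6.97 TPM. The signal recognition particle RNAs Rn7s1 and Rn7s2, whose copies share reads, had 7.40 TPM each in replicate 1 and 621 TPM each in replicate 2. Gm42418, a gene on chromosome 17 (39846958 to 39848788) chosen after its values were seen, had 9454 TPM in replicate 1 and 2302 TPM in replicate 2. Gm37376, chosen in the same way, lies within the span of Malat1 on chromosome 19 and had 2895 and 4305 TPM, so reads of the 2 genes can be exchanged.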
